A study of Mus musculus with 36 samples.

How the data were processed

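RNA-seq of mouse brain was used here without its paper. The labels give 36 libraries, from 6 brain regions of C57 mice aged 6 to 7 weeks, with 3 wild-type (WT) and 3 knock-in (KI) libraries per region. The region labels are HP, PFc, Nac, STR, SN and VTA and are not spelled out; they were read as hippocampus, prefrontal cortex, nucleus accumbens, striatum, substantia nigra and ventral tegmental area only to choose a marker list for each. The titles number the libraries of each genotype from 1 to 3 in every region. The labels do not say that libraries of a region came from separate animals, so a p-value measures the spread between these libraries, which may be technical. Per the labels' protocols the libraries were made with a SMARTER mRNA-seq kit, and per the submitters' processing notes the genome build was GRCm38.p6. The aligner, the counting tool and any use of strand are not given in the sources used here. Reads shared by near-identical or overlapping genes could therefore have been divided in ways that are not known, which concerns the ribosomal protein genes, with their many processed pseudogenes, more than most.

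The authors deposited estimated counts per gene and per transcript, which need not be whole: 9.9% of the gene values were not. They were rounded to whole numbers here before any test. The gene table lists 19025 genes, of which 18969 identifiers matched the RefSeq gene table of GRCm38.p6; symbols come from the files and coordinates from that table. Per the file headers, the authors' deposited table of gene comparisons holds log2 fold changes from DESeq2; their sign follows KI over WT in the counts. The same deposited table holds p-values and q-values from DESeq2, per the file headers, with no version or settings. A further deposited table gives the number of genes the authors called per region, which equals the number at a q-value under 0.05 in the table of comparisons. These values were used only to set the authors' calls beside those made here. A further 216 per-sample columns, and the authors' comparisons per transcript, were not used here.

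Total estimated counts ran from 15145631 to 18863503 per library. No library pair looked like a library deposited more than once. Genes were kept by edgeR's filterByExpr, normalised by TMM and tested with edgeR 4.0.16's quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each region was fitted on its own 6 libraries. Counts of the 6 regions were also summed per number in the titles, giving 3 WT and 3 KI sums. Genotype by region was tested in a 12-group fit to all 36 libraries, and region differences in WT by an F test over the 18 WT libraries. Values per group are CPM (counts scaled to a common library total) as mean ± SD. A gene is called separated where all 3 KI libraries lie on the same side of all 3 WT libraries, which chance gives for 10% of genes. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.

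Gene lists for monoamine and other transmitter pathways, for stress, metabolic and ribosomal genes, for brain cell types and for brain regions were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 3 tested members were compared with all other genes by camera on voom log2 CPM (limma), with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 198 tests of 33 lists in 6 regions. Camera with an estimated correlation was run as an alternative, and so was fry, which asks another question: whether a list's genes changed at all, not whether they changed more than other genes. A list's edgeR calls were counted over all genes and adjusted over the list alone. The rule named Maoa always. It also named, per region, the 8 largest rises and 8 largest falls among called and separated genes with a mean log2 CPM of at least 1 and a symbol that is not a predicted name, with up to 10 called list members. It took 10 and 10 over all regions, 3 genes per region in WT and 5 for genotype by region. Since edgeR called no gene between genotypes, the rule was applied to the DESeq2 calls, a choice made after the data were examined. Some genes that the rule named are not reported here.

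Each test was tried on simulated counts drawn from the real means, spreads and library sizes, with 200 genes changed. At a 4-fold change edgeR recovered 90% of changed genes in HP, 96% in PFc, 75% in Nac, 99% in STR, 91% in SN, 95% in VTA and 99% in the sums. At a 2-fold change it recovered 41%, 70%, 4%, 69%, 35%, 26% and 88% in the same order. DESeq2, on whose calls the named genes rest, recovered 88%, 92%, 83%, 98%, 92%, 94% and 97% at 4-fold and 45%, 71%, 9%, 68%, 43%, 31% and 89% at 2-fold. It made 15, 11, 17, 20, 20, 18 and 24 false calls in the same order, where edgeR made 4, 9, 2, 7, 4, 4 and 9. In the real libraries, splits otherwise than by genotype gave at most 171, 40, 597, 127, 40, 7 and 858 DESeq2 calls in that order. The simulated false calls therefore do not show how often DESeq2 calls genes falsely in these data. The steps ran on 14144 genes in HP, 14167 in PFc, 14333 in Nac, 14658 in STR, 14418 in SN, 14490 in VTA and 16171 in the sums. For a change in 1 region, the genotype-by-region test recovered 4% at 2-fold and 69% at 4-fold over 15367 genes, and the test of regions in WT recovered 65% and 91% over 15094 genes. The list test, run on 14041 genes of HP, called the 1 changed list and 0 others. In the real libraries it called 63 to 83 of 198 lists when they were split otherwise than by genotype. The simulation therefore does not show how often it calls lists falsely in these data.

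Alternatives fixed before the data were examined were DESeq2 in place of edgeR, its size factors in place of TMM, no filter beyond a count above 0, the 12-group fit in place of the region fit, the number in the title as a block, leaving out each library in turn, and, over all regions, region as a term over 36 single libraries with edgeR or with limma-voom. The marker list of each library's own region was scored as the mean log2 CPM of its members with a pseudocount of 0.5. A midpoint between the lowest and highest of the 36 libraries was then set for each list, and the 8 libraries below the midpoint of their own list were left out in further fits. That rule, those fits, robust estimation of the spread and the list tests on the sums were chosen after the data were examined. Correlations between libraries and region means used the 2000 most variable genes. Transcript lengths and GC contents came from GENCODE transcripts of GRCm38. Xist, Tsix and the mitochondrially encoded genes are not among the genes listed in the file and were not analysed here. Counts per gene do not show single bases, so the base change named in the series title was not analysed here.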

Results

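RNA was sequenced from brain tissue of wild-type (WT) mice and of mice carrying a knock-in (KI) at Maoa, the X-linked gene of monoamine oxidase A, which breaks down serotonin, noradrenaline and dopamine. The series title states that a synonymous base change lowers Maoa transcription and translation, and its design text calls the 6 regions related to addiction. Each of the regions HP, PFc, Nac, STR, SN and VTA had 3 WT and 3 KI libraries, 36 in all. Total estimated counts per library ran from 15145631 to 18863503 and were lower in KI (16.41 ± 0.69 M counts, SD, n = 18) than in WT (17.88 ± 0.47 M counts, n = 18). All 36 libraries expressed the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, with Kdm5d at 10.5 to 17.2 CPM (counts scaled to a common library total). None of these 4 genes passed edgeR's quasi-likelihood test over all regions (smallest adjusted p = 0.113, for Eif2s3y at a log2 fold change of 0.27), although DESeq2 called Eif2s3y higher.

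Maoa transcript abundance was not lower in KI past the test in any region. Maoa (gene 17161, chromosome X, 16619698 to 16687812 in GRCm38.p6) was higher in all 3 KI than in all 3 WT libraries of STR, at 65.0 ± 4.68 against 47.2 ± 2.17 CPM (log2 fold change 0.46, SE 0.109), which passed edgeR's test when adjusted over the 6 regions (adjusted p = 0.0177) but not over all genes (0.284). It was also higher in every KI library of VTA (92.2 ± 9.06 against 70.0 ± 12.6 CPM, log2 fold change 0.40, SE 0.164) and of HP (40.2 ± 5.41 against 33.5 ± 1.15, log2 fold change 0.26, SE 0.128), with adjusted p-values over the 6 regions of 0.143 and 0.166. Libraries with markers of another region widened these gaps. KI STR 3 (69.3 CPM) and KI HP 2 (46.2 CPM) were the highest KI libraries of their regions, and WT VTA 3 (55.7 CPM) the lowest WT library of VTA. The lowest log2 fold changes on leaving out a single library were 0.41 in STR, 0.26 in VTA and 0.16 in HP. PFc (0.07, SE 0.107) and Nac (0.10, SE 0.382) showed little difference, and SN alone had a lower mean in KI, at 57.7 ± 18.4 against 74.0 ± 8.60 CPM (−0.36, SE 0.237, adjusted p = 0.256). The SN value turned to 0.09 without the libraries labelled KI SN 1 and 2, and the Nac value to −0.05 without WT Nac 1 and −0.37 without KI Nac 1. Summed over the regions the log2 fold change was 0.13 (SE 0.0828), a change of 9.49% with a 95% interval of −4.27% to 25.2%. With region as a term over the 28 libraries without the 8 that carried markers of another region, taken as independent in a fit chosen after the data were examined, Maoa rose by 0.18 (adjusted p = 0.0106, over all alternatives 0.0106 to 0.714) and was higher in 6 of 6 regions. The authors' deposited table gives log2 fold changes of 0.26 in HP, 0.06 in PFc, 0.10 in Nac, 0.45 in STR, −0.36 in SN and 0.39 in VTA, with the smallest q-value, 0.0714, in STR. The file lists 1 Maoa transcript, whose counts differ from those of the gene by more than 0.01 in 0 libraries.

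**Figure D1:**
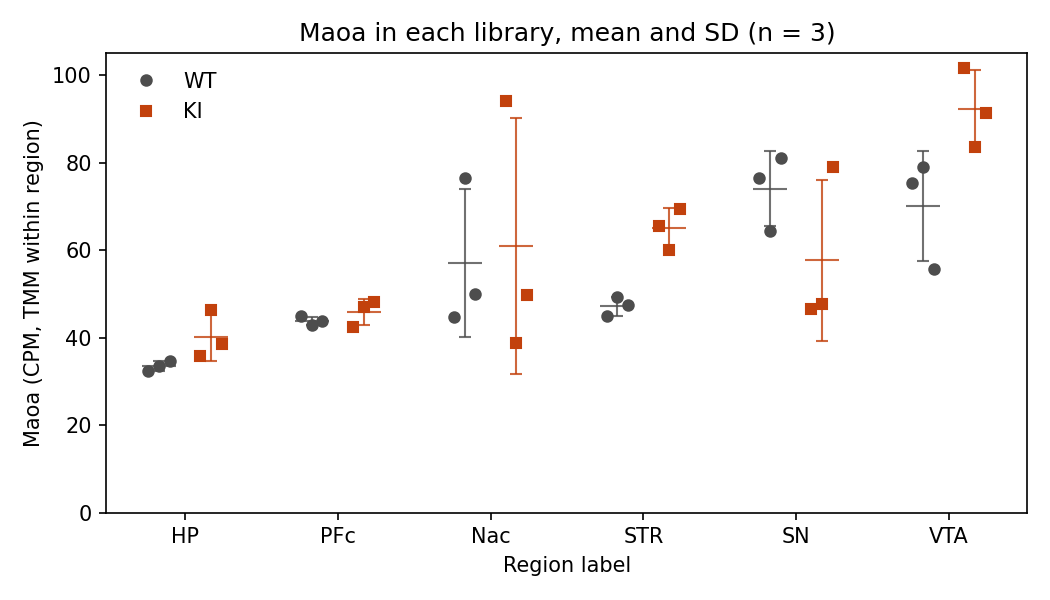
Maoa in CPM (TMM within each region) in each of the 36 libraries, by region label, with circles for WT, squares for KI, and bars for the mean and SD of 3 libraries. The KI libraries lie above the WT libraries in HP, STR and VTA, while the KI libraries of Nac and SN spread over and beyond the WT range.

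Region markers separated most libraries by label, but 8 of the 36 carried little of their own region's marker list and much of another's. The library labelled WT Nac 2 scored 4.02 on the striatal list, against 7.40 and 7.48 in the other WT Nac libraries, and 4.79 on the list of midbrain dopamine neurons; its expression of Slc6a3, the dopamine transporter, was 192 CPM, against 0.452 and 0.462 in those libraries. The library labelled WT VTA 3 scored 2.00 on the dopamine list and 7.42 on the striatal list. Among KI libraries, HP 2 and SN 2 scored 8.03 and 8.04 on the striatal list, Nac 2 had the cortical and hippocampal lists at 6.00 and 5.82, and Nac 1 had the dopamine list at 5.82, with Slc6a3 at 965 CPM. KI SN 1 had the hippocampal list at 4.54 and the dopamine list at 1.66, and KI STR 3 had the striatal list at 4.88 with the thalamic list at 6.93. Markers below the midpoint were found in 2 of 18 WT and 6 of 18 KI libraries (Fisher's exact test, two-sided p = 0.228). KI PFc 1 stayed above the midpoint of the cortical list but had the striatal list at 6.42, against 3.73 to 4.51 in the other PFc libraries. All libraries were kept under their labels, and each comparison is also given without the 8.

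**Figure D2:**
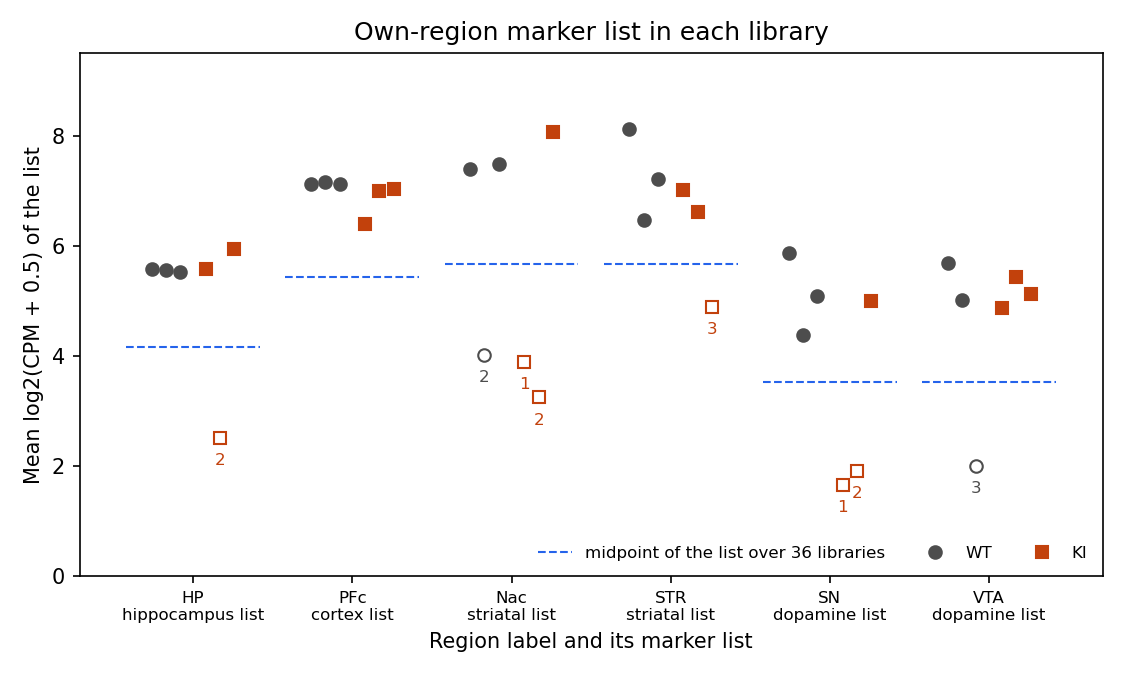
Mean log2(CPM + 0.5) of the marker list read for each region label in each of its 6 libraries, with circles for WT and squares for KI. Dashed lines mark the midpoint between the lowest and the highest of all 36 libraries on that list, and open symbols with the number in the title are the 8 libraries below it.

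Among WT libraries, the regions differed in 7249 of 15094 genes (edgeR F test over 18 libraries, adjusted p under 0.05). HP stood out for the sodium-proton exchanger gene Slc9a4 (log2 fold change over the other regions 5.67, SE 0.531), the desmosomal gene Dsp (5.37) and Lct (5.32). PFc stood out for Aldh1a3, which makes retinoic acid (4.35, SE 0.318), and the transcription factor gene Ovol2 (4.32, SE 0.560). STR had the transthyretin gene Ttr, a product of choroid plexus, at 12588 ± 2705 CPM against 200.3 in the other regions, with Kcne2 and Prr32. SN had Slc6a3 at 594 ± 431 CPM, Slc6a5, the glycine transporter of hindbrain and brainstem neurons (6.70, SE 1.01), and the midbrain transcription factor gene En1 (6.26). VTA had Slc6a4, the serotonin transporter, at 59.1 ± 58.1 CPM, and Pax7 and Ucn. Nac had the fewest genes apart from the other regions, 138 higher and 43 lower, led by Ucn (5.11 ± 8.18 CPM), Eomes (10.6 ± 10.9 CPM) and the striatal gene Serpina9 (19.5 ± 15.6 CPM), with SDs near or above the means of 3 libraries. Of these libraries WT Nac 2 carried midbrain markers, and Ucn was also among the genes of VTA. Maoa was lowest in HP (35.5 ± 1.77 CPM) and highest in SN (73.2 ± 8.84 CPM; adjusted p = 0.00169 over the regions). The count of genes differing between regions in WT fell to 2156 without the WT libraries numbered 1 and to 3836 without those numbered 2, and stood at 10671 without WT Nac 2 and VTA 3.

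In HP, genes of myelin and oligodendrocytes rose in KI by DESeq2. Mbp, encoding myelin basic protein, went from 1522 ± 304 to 5957 ± 2189 CPM (log2 fold change 1.97, SE 0.311, n = 3 per genotype), and Bcas1 (1.85), Prr18 (1.67), Mobp (1.66) and Mog (1.05) rose with it. The complement gene C1qa of microglia (0.71), the metallothionein gene Mt1 (0.83), and Qdpr, an enzyme that recycles the cofactor of monoamine synthesis (0.83), also rose. The falls were led by the transcription cofactor gene Vgll3 (−3.35, SE 0.474), Dcn, the matrix proteoglycan decorin (−2.08), the nuclear receptor gene Nr2f2 (−1.83), Npr3 (−1.53) and Kit (−1.40). Gabra2, the α2 subunit of the GABA-A receptor, fell from 189 ± 17.2 to 72.5 ± 10.1 CPM (−1.39, SE 0.172). All 15 oligodendrocyte genes had higher means in KI (median log2 fold change 0.82), 14 of them past edgeR's test adjusted over the list alone and 8 by DESeq2. All 76 cytosolic ribosomal protein genes were higher (median 0.66), 73 adjusted over the list alone, and so were all 14 microglial genes, 11 of them adjusted over the list alone. Camera called 12 lists higher and 3 lower in HP; none had an adjusted p under 0.681 with an estimated correlation. The striatal list was higher in all 17 of its members (median 3.13), and moved with the library labelled KI HP 2.

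Over all genes of HP, edgeR's quasi-likelihood test called 0 genes (smallest adjusted p = 0.304), with 2012 at an unadjusted p under 0.05 where chance gives 707. DESeq2 called 206 higher and 53 lower, and 24% of genes were separated between genotypes, against 10% by chance. Without KI HP 2, edgeR called 32 genes higher and 28 lower, with Mbp at 1.91 (adjusted p = 0.0252) and Gabra2 at −1.26 (adjusted p = 0.0111). DESeq2 then called 860, including 245 of the earlier 259 in the same direction and 20 of the 22 named genes, with Arhgap11a and Kit the exceptions.

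In PFc, genes of astrocytes and microglia and the metallothionein genes Mt1 and Mt2 rose in KI by DESeq2, and some serotonin receptor, immediate early and heat shock genes fell. Cyp26b1, which degrades retinoic acid, rose by 2.11 (SE 0.404), the Bcl-2 family gene Bok went from 42.3 ± 4.90 to 95.7 ± 5.57 CPM (1.17, SE 0.153, n = 3), and the metallothionein genes Mt1 and Mt2 rose by 1.12 and 1.11. Astrocyte genes S100b (0.86) and Aldoc (0.60) and the microglial complement gene C1qc (0.92) rose. Among serotonin receptor genes, Htr4 (−1.46) and Htr2c (−1.27) fell, as did Trhr, the receptor of thyrotropin-releasing hormone (−1.48). Npas4, an immediate early gene, fell from 41.9 ± 8.65 to 17.9 ± 1.79 CPM (−1.23, SE 0.207), and Fosb (−1.12), Fos (−1.07), Btg2 (−0.94) and Ccn1 (−0.90) fell with it. Gabra2 fell by 1.17 on the log2 scale (SE 0.256), and the matrix protease gene Adamts2 by 1.60. Prlr (−3.07) and Sostdc1 (−2.68), both on the choroid plexus list, also fell, where that list scored 4.12 in WT PFc 2 and 0.90 to 1.74 in the other 5 libraries. All 14 microglial genes had higher means (13 adjusted over the list alone), as did all 14 astrocyte genes (7 adjusted over the list alone) and all 76 ribosomal protein genes (73 adjusted over the list alone). Of 20 heat shock and chaperone genes 15 had lower means (median −0.26), and 3 fell by DESeq2. Camera called 9 lists higher and 8 lower, heat shock among the latter (adjusted p = 0.000196), none under an adjusted p of 0.681 with an estimated correlation; fry also called the dopamine and serotonin receptor list lower (adjusted p = 0.0445).

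Over all genes of PFc, edgeR called 0 (smallest adjusted p = 0.208), with 2562 at an unadjusted p under 0.05 where chance gives 708. DESeq2 called 222 higher and 140 lower, and 28.6% of genes were separated, against 10% by chance. Without KI PFc 1, which carried striatal markers, edgeR called 390 higher and 160 lower, 210 of these 550 being among the 362 DESeq2 calls of all 6 libraries; Npas4 stood at −1.23 (adjusted p = 0.0288). In that fit 13 of 15 oligodendrocyte genes were lower adjusted over the list alone, with Ermn at −1.24, while over all 6 libraries 13 of the 15 had higher means (median 0.30) and camera did not call the list (adjusted p = 0.769), so its direction turned with KI PFc 1.

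In Nac, 3 of the 6 libraries had markers of another region, and few genes differed by label. Rgs5, a pericyte gene, rose from 70.7 ± 2.59 to 121 ± 5.79 CPM by DESeq2 (0.78, SE 0.162, n = 3). The only other DESeq2 call was the predicted gene Gm14685, named after its values were seen, at 1.16 ± 0.298 CPM in WT and 0 counts in the 3 KI libraries. By list, all 14 microglial genes (median 0.52) and all 9 tested pericyte genes (median 0.38) had higher means in KI, and 0 of 13 thalamic genes did; adjusted over the list alone, 0 microglial, 1 pericyte and 0 thalamic genes passed. WT Nac 2 scored 5.79 on the thalamic list, and without the 3 libraries camera did not call it (adjusted p = 0.0661). Camera called 9 lists higher and 6 lower, none under an adjusted p of 0.681 with an estimated correlation. Over all genes edgeR called 0 (smallest adjusted p = 0.9998), with 146 at an unadjusted p under 0.05 where chance gives 717, and 4.1% of genes were separated, against 10% by chance. Without WT Nac 2, KI Nac 1 and KI Nac 2, which leaves 1 KI library assumed to vary like the others, edgeR called 0 with 1504 at an unadjusted p under 0.05, and DESeq2 called 81, none of them shared with the earlier 2.

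In STR, single genes of receptors and channels rose or fell in KI by DESeq2, while camera did not call the GABA-A receptor list (adjusted p = 0.237). Chrnb3, the β3 subunit of nicotinic receptors, rose to 5.32 ± 3.01 CPM (3.64, SE 0.680, n = 3), the GABA-A subunit genes Gabre and Gabrq by 2.62 and 2.14, and the calcitonin receptor gene Calcr by 2.26. Irs4 (2.77), Prph (2.74) and Gpr151 (2.35) rose too, along with Gbx2, a thalamic transcription factor gene (1.15). Falls were led by Colq, the collagen tail of acetylcholinesterase, from 7.15 ± 2.54 to 1.67 ± 0.309 CPM (−2.11, SE 0.366), Syt2, a calcium sensor of transmitter release (−1.46, SE 0.246), the potassium channel subunit gene Kcnab3 (−1.29), Cplx3 (−1.22) and Lgi2 (−1.22). Gabrd, the δ subunit of GABA-A receptors, fell by 0.95 (SE 0.172). All 20 striatal medium spiny neuron genes had lower means in KI (median −1.12) but none passed adjusted over the list alone, and KI STR 3 scored 4.88 against 6.47 to 8.12 in the other libraries. Without KI STR 3 camera still called the list lower (adjusted p = 0.00219; 0.744 with an estimated correlation). Of 10 tested hypothalamic genes 7 had higher means (median 1.36), 4 of them past the test adjusted over the list alone, with KI STR 3 at 2.67 and KI STR 1 at 1.81 on that list against 0.61 to 1.01 in WT; camera did not call it (adjusted p = 0.0974). The heat shock and chaperone list was lower in 20 of 20 members (median −0.29), with 0 passing adjusted over the list alone. Camera called 3 lists higher and 8 lower, none under an adjusted p of 0.681 with an estimated correlation.

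Over all genes of STR, edgeR called 0 (smallest adjusted p = 0.251), with 1580 at an unadjusted p under 0.05 where chance gives 733. Another split of the same libraries, with KI STR 3 beside WT STR 1 and 2, gave 1679, so this excess cannot be credited to genotype. DESeq2 called 132 higher and 78 lower, and 17.6% of genes were separated, against 10% by chance. Leaving out WT STR 2 gave 2 edgeR calls. Without KI STR 3 edgeR called 0, with 1456 at an unadjusted p under 0.05, and DESeq2 called 215, sharing 129 of the 210 and 18 of the 25 named genes; Gbx2 (1.19), Colq (−2.26) and Syt2 (−1.65) were among these, while Irs4 and Prph were not.

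In SN, the libraries labelled KI differed from WT in neuron type markers, and 2 of the 3, KI SN 1 and KI SN 2, scored low on the dopamine list (1.66 and 1.91, against 4.38 to 5.86 in the other libraries). Of 23 tested genes of monoamine synthesis, transport and breakdown, 4 fell by DESeq2 and 17 had lower means (camera adjusted p = 0.000219; 0.706 with an estimated correlation), and without KI SN 1 and 2 camera did not call that list (adjusted p = 0.669). By DESeq2, Slc6a5 went from 79.1 ± 55.1 to 0.417 ± 0.448 CPM (−7.57, SE 1.04, n = 3), Mab21l2 fell by 6.12, Dbh, the last enzyme of noradrenaline synthesis, by 4.39, and Tph2, the enzyme of serotonin synthesis in neurons, by 3.72. Slc6a2, the noradrenaline transporter, was at 3.16 ± 2.24 CPM in WT and at 0 counts in all 3 KI libraries. Rises were led by Dio3 (5.23, SE 0.809), Crym (5.03), Lrrc10b (4.71), the ependymal gene Ccdc153 (4.64), the hippocampal gene Spink8 (4.62) and the dopamine receptor gene Drd1, from 3.08 ± 0.588 to 70.0 ± 102 CPM (4.51, SE 1.30). The astrocyte glutamate transporters Slc1a3 (1.03) and Slc1a2 (0.96) rose, while 11 of the 14 astrocyte genes had lower means (median −0.33) and camera did not call that list (adjusted p = 0.380); without KI SN 1 and 2 camera called it higher (adjusted p = 0.0182; 0.646 with an estimated correlation). Of 24 immediate early genes 18 had higher means and 5 rose by DESeq2. Camera called that list higher (adjusted p = 0.00497, and 0.710 with an estimated correlation). The list pointed the same way without KI SN 1 and 2, a fit that leaves 1 KI library. All 19 tested striatal genes had higher means (15 adjusted over the list alone), and 15 of 20 dopamine neuron genes lower means (median −1.82, none adjusted over the list alone). Without KI SN 1 and 2, which leaves 1 KI library, the striatal list still pointed higher. The dopamine neuron list then had no clear direction, pointing higher by camera and lower by fry. Camera called 5 lists higher and 6 lower, none under an adjusted p of 0.681 with an estimated correlation.

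Over all genes of SN, edgeR called 0 (smallest adjusted p = 0.122), with 2531 at an unadjusted p under 0.05 where chance gives 721. DESeq2 called 548 higher and 442 lower, and 24.2% of genes were separated, against 10% by chance. Leaving out KI SN 3, which kept the SN markers, gave 383 edgeR calls (168 higher and 215 lower). Without KI SN 1 and 2, which leaves 1 KI library assumed to vary like the others, edgeR called 0 with 1565 at an unadjusted p under 0.05, and DESeq2 called 206, sharing 140 of the 990 and 11 of the 24 named genes. Slc6a5 (−6.43) and Drd1 (2.52) were among these, while Tph2, Dbh, Dio3, Crym and Slc1a3 were not.

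In VTA, the lists of vessel, meningeal, oligodendrocyte and astrocyte genes were higher in KI by camera, though with an adjusted p of at least 0.681 with an estimated correlation, and single subunit genes of GABA-A and glutamate receptors fell by DESeq2. By DESeq2, Col3a1 (1.43), Col1a2 (0.94) and Igf2 (1.25), from the meninges and fibroblast list, rose, as did the pericyte gene Rgs5 (0.87), the endothelial genes Slco1a4 (1.01) and Itm2a (0.81), Mbp (1.21) and Gfap, the astrocyte filament gene, from 343 ± 74.9 to 865 ± 220 CPM (1.33, SE 0.259, n = 3). Cbln3, made by cerebellar granule cells, rose by 5.11 (SE 1.19), from 0.823 ± 0.518 to 28.7 ± 27.4 CPM. Gabra2 fell from 87.8 ± 38.4 to 34.5 ± 2.59 CPM (−1.35, SE 0.311), and Gabra5 (−0.93), Grin2a (−0.71) and Grin1 (−0.57) fell. Dbh and Slc6a2 rose, by 3.66 and 3.60. All 11 fibroblast genes (7 adjusted over the list alone), all 12 endothelial genes (8), all 10 pericyte genes (4), all 15 oligodendrocyte genes (7) and 13 of 14 astrocyte genes (8) had higher means. The GABA-A list, with 2 of 14 members falling by DESeq2, was called lower by camera (adjusted p = 0.00916) but not without WT VTA 3 (0.130), and the ionotropic glutamate list, with 2 of 18, was called lower in both (0.00546 and 0.00769), although Grin2c rose without that library (0.69, edgeR adjusted p = 0.0257). Camera called 14 lists higher and 8 lower, none under an adjusted p of 0.681 with an estimated correlation; fry called the cortical list lower (adjusted p = 0.000641), on which WT VTA 3 scored 4.69 and the other WT libraries 4.37 and 4.41. Striatal genes were lower in KI in 19 of 19 members (median −1.84); without WT VTA 3, which carried striatal markers, the median was −0.23, and camera still called the list lower (adjusted p = 0.0360; 0.646 with an estimated correlation).

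Over all genes of VTA, edgeR called 0 (smallest adjusted p = 0.355), with 1879 at an unadjusted p under 0.05 where chance gives 724. DESeq2 called 120 higher and 65 lower, and 23.4% of genes were separated, against 10% by chance. Without WT VTA 3, edgeR called 525 higher and 313 lower, including 168 of the 185 DESeq2 calls, with Rgs5 at 1.02 (adjusted p = 0.0189), Gabra2 at −0.93 (0.0189) and Mbp at 1.39 (0.0243). DESeq2 then called 1798, including 175 of the 185 and 24 of the 25 named genes; Asic4 was the exception, and Actn2 and Cpne5 moved from −2.87 and −2.08 to −1.14 and −0.91.

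Counts were summed over the 6 regions per number in the titles, so an exchange of libraries between numbers would alter the sums. The myelin genes Mbp and Bcas1 were among the rises in KI, although the oligodendrocyte list was not called on the sums and was called lower in SN (adjusted p = 2.77e-05; 0.710 with an estimated correlation). By DESeq2, Mbp rose from 4490 ± 123 to 9590 ± 2210 CPM (1.10, SE 0.163, n = 3), Bcas1 by 1.11, the habenular receptor gene Gpr151 by 1.59, Trak2 by 0.92 and the cold-induced RNA-binding protein gene Rbm3 from 52.8 ± 0.489 to 94.4 ± 9.69 CPM (0.84, SE 0.0972). The vessel genes Rgs5 (0.64), Slco1a4 (0.63) and Itm2a (0.54) rose. Colq fell by 1.34 (SE 0.182), Syt2 by 1.25, the lipid droplet gene Plin4 by 1.07, Nefh, the heavy neurofilament, by 0.97, and Sgpp2, a sphingosine-phosphate phosphatase, from 40.5 ± 3.42 to 20.96 ± 1.16 CPM (−0.95, SE 0.0979). Among GABA-A subunit genes, Gabra2 fell by 0.94 (SE 0.110) and Gabrb2 by 0.54. Gm14685, named after its values were seen, fell by 3.21 (SE 0.517), from 1.14 ± 0.315 to 0.123 ± 0.106 CPM. Over all genes edgeR called 0 (smallest adjusted p = 0.0543), with 3210 at an unadjusted p under 0.05 where chance gives 809, while DESeq2 called 638 higher and 718 lower and 26.4% of genes were separated, against 10% by chance. A split that exchanged the sums numbered WT 3 and KI 1 gave 2797 at that unadjusted p, and 858 DESeq2 calls. With region as a term over 36 libraries taken as independent, edgeR called 1455 genes, and 2619 without the 8 libraries, of which 1278 were shared with the 1455. Without the sums numbered KI 2, edgeR called 10 genes.

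On the sums, all 76 ribosomal protein genes had higher means in KI (median 0.35), and 72 rose by DESeq2 and by edgeR adjusted over the list alone. Camera called the list higher (adjusted p = 7.36e-45; 0.473 with an estimated correlation). The rise was not shown in every region. Without the 8 libraries camera called the list higher in HP, PFc and VTA (0.646 in each with an estimated correlation). It did not call the list in STR (adjusted p = 0.538), and Nac and SN then kept 1 KI library each. All 14 microglial genes were higher (median 0.34, 12 adjusted over the list alone, camera adjusted p = 5.39e-09), as were all 12 endothelial genes (median 0.35, 10 adjusted over the list alone, 5.52e-09) and 9 of 10 pericyte genes (6 adjusted over the list alone, 2.12e-05). With an estimated correlation these adjusted p-values were 0.487, 0.460 and 0.358. All 20 heat shock and chaperone genes had lower means (median −0.22), 14 adjusted over the list alone, with Hspa1b (−0.45) and Dnajb1 (−0.40) among 8 that fell by DESeq2 (camera adjusted p = 5.39e-09; 0.487 with an estimated correlation). Of 24 immediate early genes 20 had lower means, and Npas4 (−0.71), Fos (−0.51), Dusp1 (−0.42) and Ccn1 (−0.36) fell by DESeq2 (camera adjusted p = 0.00139; 0.487 with an estimated correlation), whereas in SN that list was called higher. Astrocyte (14 of 14 higher), oligodendrocyte precursor (8 of 9), oxidative phosphorylation (52 of 72) and hippocampal (16 of 17) lists were also called higher and the cortical list lower, at adjusted p-values of 0.000256, 0.0335, 0.00669, 0.00476 and 0.00751; with an estimated correlation these were 0.487, 0.487, 0.884, 0.460 and 0.473. KI SN 1 and KI STR 3 scored 4.54 and 4.30 on the hippocampal list, and over the 28 libraries without the 8 its median was 0.06, with 1 of 17 genes called. Fry called 4 of the 35 lists: pericyte (0.0207), endothelial (0.0290), ribosomal (0.0370) and hippocampal (0.0497). The list of monoamine synthesis, transport and breakdown was not called (camera adjusted p = 0.936, 9 of 25 higher); Qdpr was its only DESeq2 call (0.42). Lists of dopamine and serotonin (0.589), adrenergic (0.133), ionotropic glutamate (0.117) and GABA-A receptors (0.122) and of opioid peptides and receptors (0.936) were not called either. Nor were those of the circadian clock (0.0659), glucocorticoid response (0.374), antioxidant defence (0.936), interferon response (0.387), oligodendrocytes (0.133) or sex-linked genes (0.936). The lists of meninges (0.0858), choroid plexus (0.0890), ependyma (0.315), blood (0.510), pituitary (0.936), thalamus (0.0526) and hypothalamus (0.884), and of striatal (0.322), dopamine (0.936), serotonin (0.234) and noradrenaline neurons (0.322), also missed the threshold. Of 20 genes near Maoa (0.322), Gpr34 (0.41) rose and Slc9a7 (−0.32) and Uba1 (−0.20) fell by DESeq2, and none passed edgeR adjusted over the list alone.

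Nnt, encoding the mitochondrial nicotinamide nucleotide transhydrogenase, was singled out after its values were seen. In the sums it was 20.9 ± 0.164 CPM in KI and 29.9 ± 0.310 in WT (log2 fold change −0.52, SE 0.0544, n = 3, edgeR adjusted p = 0.0543; DESeq2 adjusted p = 2.52e-11). Its mean was lower in KI in all 6 regions, from −0.28 in SN to −0.72 in STR, with genotypes separated in every region but SN. Gabra2 (chromosome 5, 70958392 to 71095849) was separated in HP, PFc, STR and VTA, and stood at 0.16 (SE 0.302) in SN; without the 8 libraries its mean was lower in KI in 6 of 6 regions, of which Nac and SN kept 1 KI library each. Nnt lies on chromosome 13, 119335527 to 119409257.

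**Figure D3:**
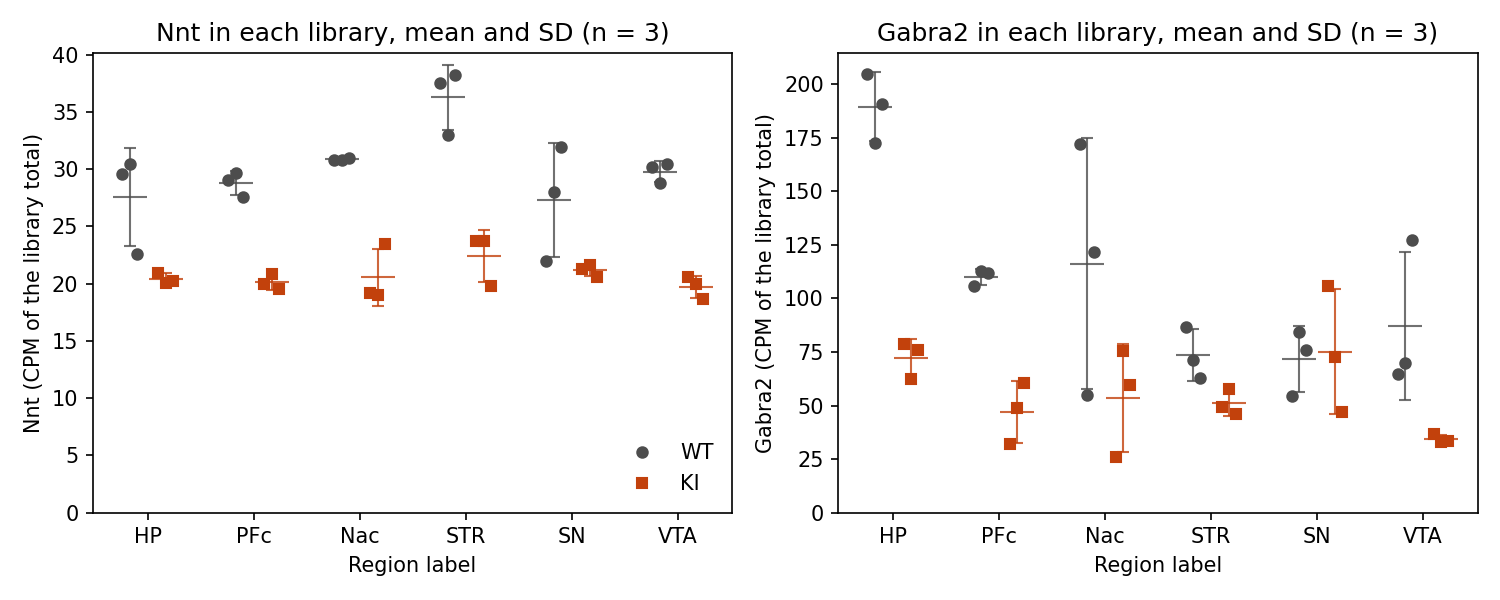
Nnt and Gabra2 in CPM of the library total in each of the 36 libraries, by region label, with circles for WT, squares for KI, and bars for the mean and SD of 3 libraries. KI means lie below WT means in all regions for Nnt, and in all but SN for Gabra2.

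Whether the difference between genotypes itself differed between regions was tested over all 36 libraries. The genes with the smallest adjusted p were Lrrc55, at 1.19 in STR and −1.02 in SN, Prr36, Tcf24, Odf3l2 and Lbx1. None passed: edgeR called 0 of 15367 genes (smallest adjusted p = 0.344), with 1341 at an unadjusted p under 0.05 where chance gives 768. It called 8 without the 8 libraries and 2 without the KI libraries numbered 1. A gene called in 1 region and not in another is therefore not shown to differ between them. Maoa had an adjusted p of 0.602 in this test.

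The authors' deposited table lists 185 genes in HP, 280 in PFc, 2 in Nac, 200 in STR, 934 in SN and 154 in VTA at a q-value under 0.05. Of these, 178, 277, 2, 200, 933 and 152 were also called by DESeq2 here. Of all the genes in the authors' lists, 148, 169, 1, 123, 518 and 106 were higher in KI, in the same order.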

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

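The tests on the 8 libraries with markers of another region and all tests on Nnt and Gabra2 were chosen only after the result was seen, as was leaving those libraries out in the test on ribosomal genes.

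Among 116 named genes, 26 were separated between genotypes in opposite directions in different regions, which is what marked them; the gap between the highest and lowest log2 fold change follows each gene given here, where highest and lowest hold only among the regions in which that gene was separated. Over all genes tested in every region, 1345 of 13699 did so. Chance separates 10% of genes in a single region, in either direction. That is not the share it would separate in opposite directions in different regions, which was not worked out. The genotype-by-region test passed for none of the 26 (edgeR, smallest adjusted p = 0.528; over all 15367 genes 0 passed and 1341 had an unadjusted p under 0.05), so no difference between regions is shown for them. Highest in VTA and lowest in SN were the noradrenaline genes Slc6a2 (12.24, a fitted value that depends on the prior count since SN had 0 counts in KI) and Dbh (7.86), and Car13 (3.64). Actn2 (6.31) and the GABA-A subunit gene Gabra5 (2.38) were highest in SN and lowest in VTA. Highest in STR were Calcr (4.43) and Gabrq (2.39), lowest in VTA; Bmp3 (3.79), Nr4a2 (2.47) and Car10 (2.11), lowest in HP; and Trhr (3.33), AW551984 (2.72) and Htr4 (1.76), lowest in PFc. Gabre (3.60) was highest in STR and lowest in Nac, and Rasgrf2 (1.82) highest in STR and lowest in SN. Dcn (2.62), Nr2f2 (2.46) and Npr3 (2.13) were highest in VTA and lowest in HP. Gabrd (1.99) and Gpx1 (1.12) were highest in HP and lowest in STR. Spp1 (4.22) and Esrrb (2.72) were highest in PFc and lowest in SN, and Neu2 (2.22) highest in PFc and lowest in VTA. The ependymal gene Ccdc153 (6.86) was highest in SN and lowest in PFc, and Car12 (4.94) highest in SN and lowest in STR. Every region but PFc held some of the 8 libraries with markers of another region, and KI PFc 1 carried striatal markers. Without the 8, Actn2 in VTA went from −2.87 to −1.14 by DESeq2. Ccdc153 in SN, with 1 KI library left, went from 4.64 to 2.21. Others held, such as Dcn in HP (−2.08 to −2.20) and Calcr in STR (2.26 to 2.47). How far these libraries make the gaps was not tested.

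Markers of another region were found in 8 libraries, and 6 of them reach the correlation of kept libraries with another region's mean; a first version of that rule gave 5, and KI Nac 1 (0.819 with VTA) was added by its level in SN. Tissue of another region mixed into the labelled one was looked for in these 6. None showed it, since 0 of them had more of their own list than the highest kept library of the nearest region. This cannot argue against mixing, because the 6 were picked for little of their own list and a profile reaching another region. WT Nac 2 and KI Nac 1, at 4.02 and 3.89, also lay close to that highest library, at 4.05. Mixed tissue therefore stays open for the 6. An effect of the knock-in on region markers is argued against as the whole cause, since 2 of the 8 are WT libraries, both below the midpoint by more than the SD. Region labels exchanged between libraries remain a candidate explanation for the 6, since all 6 have a partner bearing the label they reach: WT Nac 2 with WT VTA 3, KI HP 2 with KI Nac 2, and KI Nac 1 with KI SN 2. KI SN 2 was a partner of WT Nac 2 as well, so the pairs are not unique. KI Nac 1 missed the level of VTA (0.846). It reached that of SN (0.776 against 0.457), which KI SN 3 alone set and all kept VTA libraries also reached. Its pairing is therefore the least certain. For KI SN 1 and KI STR 3, an exchange is argued against by a correlation at least 0.266 below any other region's libraries, while tissue of another region mixed in remains open: 2 of these 2 libraries carried a list of another region, but KI SN 1 had little of its own list (1.66).

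Nnt and Gabra2 were lower in KI. A genomic segment carried along with Maoa is argued against, since 0 of the 2 genes lie on chromosome X, and so are the libraries with markers of another region, since Nnt stood at −0.47 without them (95% interval −0.58 to −0.35, lower in KI in 6 of 6 regions). C57BL/6J mice carry known variants that lower Nnt and Gabra2, and the labels say only C57, so mice of different C57BL/6 substrains are a candidate explanation, which cannot be told apart here from the knock-in because every KI library may share it. The bound written against it, 9 or fewer of 18 KI libraries below the lowest WT library in Nnt, was met at 9, but 1 library, WT SN 1 at 21.4 CPM, set it; without it the count is 17 of 18, and the rule was changed to leave the question open after that value was seen. Scaled by library totals alone, 3 KI libraries (23.4, 23.7 and 23.7 CPM) lie above that WT library (22.0 CPM), and Gabra2 stood at 0.16 in SN with KI SN 1 and 2 included but was lower in KI in 6 of 6 regions without the 8 libraries. For both genes, Nac and SN then kept 1 KI library each.

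Cytosolic ribosomal protein genes were higher in KI sums, with a median log2 fold change of 0.35 (quartiles 0.30 and 0.42) over 76 genes. Of the 18 KI libraries, 12 had a mean log2 CPM of the list above the highest WT library of their region. GC content, and transcript length in part, is argued against by a median of 0.07 in 212 other genes matched on length, GC and level. Lengths were those of the longest transcript of each gene, which need not be the one expressed. The matched genes were longer (median 1438 against 1100 bases) and lower in level (median log2 CPM 7.61 against 8.05). Over all other genes the median was 0.05 in the shortest of 5 length groups and −0.05 in the longest. A length effect on the RNA sequenced therefore stays open. The libraries with markers of another region are argued against by a fit with region as a term over single libraries. There the median was 0.38 over all 36 libraries and 0.39 without the 8. Lower depth of the KI libraries stays open: the median was 0.35 after every library was thinned to the shallowest, but thinning keeps proportions and moved the matched genes by a median of only 0.00305 (log2), so the bound written against depth was wrong and was set aside after the value was seen. Reads shared with processed pseudogenes, a difference in cell composition or tissue handling between genotypes, and the genotype itself remain open and untested.

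Of the splits of the same libraries into groups of equal size, 10 exist in each region and for the sums, too few for a share under 0.05. EdgeR called 0 genes in the real split of every region and of the sums, and at most 58 in another split of Nac, 20 of STR and 0 elsewhere. At an unadjusted p under 0.05 the real counts and the highest others were 2012 and 1538 in HP, 2562 and 1087 in PFc, and 146 and 1647 in Nac. They were 1580 and 1679 in STR, 2531 and 1080 in SN, 1879 and 1362 in VTA, and 3210 and 2797 in the sums. The counts said above to be given by chance are a share of the genes tested. The highest other split exceeded that share in every region and in the sums, while most other splits lay below it. By DESeq2 the real counts and the highest others were 259 and 171 in HP, 362 and 40 in PFc, 210 and 127 in STR, 990 and 40 in SN, 185 and 7 in VTA, and 1356 and 858 in the sums. In Nac the real split gave 2, 7 of the 10 splits gave as many, and 1 gave 597. That split set WT Nac 1, WT Nac 3 and KI Nac 3 against WT Nac 2, KI Nac 1 and KI Nac 2, which carried markers of another region. The structure of these samples thus follows the region markers rather than genotype. Camera called 91 of 198 lists in the real split and 63 to 83 in the others. For genotype by region all 80 splits drawn gave 0 genes by edgeR like the real split, which decides nothing, since every count is at least 0; at an unadjusted p under 0.05 the real split had 1341 genes and the highest other 3035. For regions in WT, 1 of 100 splits drawn, the real split, gave 7249 genes and the highest other 165, so chance can be excluded.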

How the results depend on the processing

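The alternatives without the libraries below the midpoint of their region list were chosen only after the result was seen; the cause of a change was not tested unless stated. Of 271 values of comparisons and Maoa, 224 stayed the same: Maoa kept direction and side of the threshold, and counts stayed equal or close. Of 2170 values of named genes, 1721 kept direction and side, which here means that they stayed uncalled. EdgeR called none of the named genes in the main fit, and DESeq2 called all 152 pairs of gene and comparison. DESeq2's size factors in edgeR gave calls for 0 of 152, no filter for 4 and the number as a block for 3. The 12-group fit gave calls for 0 of 123. DESeq2 in place of edgeR called 259 genes in HP, 362 in PFc, 2 in Nac, 210 in STR, 990 in SN, 185 in VTA and 1356 over all regions, where edgeR called 0. The 12-group fit called 1 in STR and 2 in VTA. No filter gave 5 over all regions, the region term over 36 libraries 1455, and limma-voom 1409, with Lct at −0.74. Without the libraries below the midpoint, fewer samples were fitted: region fits called 60 in HP and 838 in VTA, the 12-group fit 12 in HP, 860 in PFc, 85 in STR, 343 in SN and 329 in VTA, DESeq2 860 in HP, 81 in Nac, 215 in STR, 206 in SN and 1798 in VTA, the region term 2619, and genotype by region 8. Maoa over all regions was then 0.18 (adjusted p = 0.0106, over alternatives 0.0106 to 0.714), and Maoa in SN 0.10 in the 12-group fit, 0.0895 in the region fit and 0.0858 by DESeq2. Camera with an estimated correlation called 0 lists and fry 2, against 91. Numbers in the titles do not pair the WT and KI libraries of a region (2 of 18 same-number pairs correlated above 0.1); with the number as a block, SN had 13 genes (6 higher, 7 lower). Libraries of the same genotype and number in different regions had a median correlation of 0.00853, against −0.00364 for other numbers. The sums are therefore not shown to stand for single animals. Leaving out single libraries in region fits, or all libraries of a genotype with the same number elsewhere, gave 0 to 60 genes in HP (60 without KI 2), 0 to 550 in PFc (KI 1), 0 in Nac, 0 to 2 in STR (WT 2), 0 to 383 in SN (KI 3), 0 to 838 in VTA (WT 3), 0 to 10 over all regions (KI 2), 0 to 2 for genotype by region (KI 1), 2156 to 5897 for regions in WT and 82 to 100 lists. Maoa then lay at 0.16 to 0.33 in HP, 0.03 to 0.12 in PFc, −0.37 (without KI 1; −0.05 without WT 1) to 0.36 in Nac, 0.41 to 0.51 in STR, −0.65 to −0.22 in SN, 0.26 to 0.49 in VTA and 0.10 to 0.22 over all regions. Its transcript lay at 0.15 to 0.35 in HP, 0.02 to 0.10 in PFc, −0.40 (without KI 1; −0.06 and −0.01 without WT 1 and WT 3) to 0.35 in Nac, 0.41 to 0.51 in STR, −0.67 to −0.25 in SN and 0.25 to 0.50 in VTA. Depth was lower in KI, and what it limits was not tested.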

Other observations

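The fit without the 8 libraries with markers of another region was chosen only after the result was seen. On the sums of all 36 libraries per number in the titles, edgeR called 0 genes (smallest adjusted p = 0.0543). The edgeR calls given here were thus not made there.

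Region was a term over the 28 remaining libraries (12 KI and 16 WT, taken as independent). EdgeR called 14 of 14 microglial, 10 of 12 endothelial, 10 of 14 astrocyte and 67 of 76 ribosomal protein genes higher in KI. It called 3 of 15 oligodendrocyte genes higher (median log2 fold change of the list 0.31) and 14 of 20 heat shock and chaperone genes lower. Differences between lists were not tested. The rises named next had higher means in 6 of 6 regions, of which Nac and SN kept 1 KI library each. The microglial receptor genes Cx3cr1 (log2 fold change 0.59, SE 0.0775), Trem2 (0.70, SE 0.123) and Csf1r (0.54, SE 0.0946) rose, as did the pericyte genes Rgs5 (0.67) and Pdgfrb (0.52) and the endothelial gene Itm2a (0.63). Bcas1 (1.16), Mbp (1.16, SE 0.218), Trak2 (1.07), the chemokine gene Ccl9 (1.03) and Sytl5, a vesicle trafficking gene (1.49, SE 0.290), rose too. Falls with lower means in 6 of 6 regions included Gabra2 (−0.94, SE 0.107), the lipoxygenase gene Alox12b (SE 0.221, adjusted p = 0.00380), Sptssb, a subunit of serine palmitoyltransferase (−0.90, SE 0.172), and the chaperone genes Hsp90aa1 (−0.33) and Dnajb1 (−0.37). Maob, the other monoamine oxidase gene, stood at 0.21 (adjusted p = 0.115, higher in 4 of 6 regions).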
